A study of Mus musculus with 8 samples.

How the data were processed

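The samples were 8 genomic DNA libraries of CH12 cells, a mouse B cell line, that stably expressed the nuclease Cas9 and carried a genome-wide guide RNA library (mBrie). Per the labels' protocols, all cultures were selected with puromycin for 15 days and stimulated with IL-4, TGF-beta and an antibody against CD40 for 72 h. IgM+ and IgA+ cells were then separated with antibody-coupled magnetic beads before DNA was extracted. Each group has 4 libraries, numbered 1 to 4 in their titles. Nothing in the labels says whether the replicates were separate transductions. The p-values of tests that compare libraries thus measure only the spread between these libraries, which may be technical. Those of the rank test and of the gene lists, described below, compare guides or genes with other guides or genes.

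The authors deposited raw read counts per guide for 79635 guides, whole numbers that were not normalized. The name of this table calls its counts ambiguous, and what that means for the reads counted is not given in the sources used here. They also deposited a gene table with a score, p-values, a false discovery rate (FDR), a rank, a number of supporting guides and a log2 fold for each gene and direction. The submitters' processing notes name MAGeCK and the mouse build mm9, and the MAGeCK version is not given in the sources used here. The other quantities of the deposited gene table, such as ranks and guide numbers, are used as the authors gave them. All 8 library columns of the count table were used.

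The tables used here do not pair guides with genes, and no reference genome was used. The planned tests on genes were therefore replaced, after the files were seen, by tests on runs of 4 guides with consecutive numbers. Overlapping runs past the threshold were merged and counted as 1. Genes are named from the authors' deposited table, and no gene was named from a guide's number or its place in an annotation. The 1000 control guides were located by sliding the deposited folds of the control rows along the whole count table. Over 78636 placements the correlation with the recomputed folds, across guides, was 0.949 at guide 78634 and at most 0.145 elsewhere. The deposited folds of these controls followed the mean of the 4 same-number log2 ratios, with a median absolute difference of 0.011. The formula behind the deposited folds was not given in the sources used here.

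For 3 genes the guides were assigned by value, a step chosen after seeing the data; 1 of them is reported here, and some other genes are not reported here either. Genes were taken from the largest deposited log2 fold down. A gene was assigned where exactly 1 run, with a mean of at least 50 reads for each guide, had a median log2 ratio within 0.05 of its deposited fold. The procedure stopped at the first gene for which this failed, Irf4, where 0 runs lay within 0.05 of the deposited fold. An earlier attempt with a tolerance of 0.12 had also assigned Irf4, but 2 overlapping runs lay within it, so that assignment was dropped. The same rule assigned 0 genes at a tolerance of 0.02, 3 genes at 0.1 and at 0.12, and 2 genes at 0.2. These assignments are inferences from values, not entries of a file.

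Guides with a mean of at least 10 reads over the 8 libraries were kept, 78708 in all. IgM and IgA libraries were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, Benjamini-Hochberg adjustment) in R 4.3.3, for guides and for counts summed over runs. A rank test over the guides of a run followed the alpha-RRA scheme of MAGeCK, rewritten here, with an alpha of 0.1, at least 2 kept guides per run and 1000000 random sets per set size. Every log2 fold is IgM minus IgA, so a positive value means more guide reads in IgM+ cells. Log2 ratios of single guides used a pseudocount of 1, and those of summed guides none. CPM stands for reads scaled to the TMM-adjusted library size. The threshold was an adjusted p or FDR of 0.05. Runs overlap and share guides, so the adjustment over runs is approximate.

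Whether the replicate numbers pair the samples was judged from the counts, not from the calls. Deviations from the group means, across guides, correlated at 0.73 to 0.787 between libraries of the same number and at -0.347 to -0.129 between libraries of different numbers. Subtracting the mean of 4 libraries itself pushes the latter values below 0. Without this step, log2 CPM correlated at 0.903 to 0.919 between IgA and IgM libraries of the same number. Between IgA and IgM libraries of different numbers it correlated at 0.596 to 0.687. The numbers thus pair the samples. The design fixed beforehand has no block, and values with the replicate number as a block are given beside those results that it changed.

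Gene lists fixed before the data were examined were tested with cameraPR (limma 3.58.1, preset correlation 0.01) on a z from the deposited p-values. Only the lists were fixed beforehand. This test took the place, after the files were seen, of the planned camera test on counts summed over each gene's guides. The z came from the smaller p of the 2 directions, signed toward IgM or IgA. Where both p-values lay above the middle of their range, its sign turned the other way. With the deposited log2 fold in its place, all 9 lists that passed still passed, in the same direction. No correlation could be estimated, because the guides of the genes were not known. The proteasome list was formed by name prefix and so also holds Psmc3ip, which is not a proteasome subunit. Named genes follow a rule fixed beforehand: up to 15 with the smallest p toward IgM, up to 10 toward IgA (the 5 smallest where fewer than 5 passed), list members past the threshold or up to 2 per list, and 10 landmark genes of class switching. The deposited p took the place of the planned rank test. Genes named outside this rule are said to be so.

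Total reads per library lay between 24157439 and 35747242. Binomial intervals are exact (Clopper-Pearson) at 95%, floors stand for 3 reads, and both cover counting error only, since PCR reads are not independent molecules. In counts simulated from these libraries with 200 changed runs, of 50 per fold size, the rank test without block recovered 98% of runs raised by 1 log2 unit and 92% of those lowered by 1, and called 9 unchanged runs. Without block, the test on summed counts recovered 0% of runs changed by 1 log2 unit and 68% of those changed by 2. The guide test without block recovered 0% of guides raised or lowered by 1 or 2 log2 units. With the block it recovered 70.9% of those raised by 1 and 45% of those lowered by 1. With the block it also called 29 unchanged guides among 637 calls, and the test on summed counts called 34 unchanged runs. The simulation gave all guides of a changed run the same fold and no drift of the fold with read number. Recovery and false calls in the real counts may therefore differ. Alternatives covered scaling, the read minimum, DESeq2 1.42.0, the block, fry, the rank test's settings and left-out libraries. Figures were drawn with matplotlib 3.10.9.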

Results

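Guide RNA abundance was compared between IgM+ and IgA+ cells of the mouse B cell line CH12 to find genes involved in class switch recombination, the DNA rearrangement by which a B cell replaces IgM with another isotype such as IgA. A guide against a gene that switching needs should be more abundant among cells that stayed IgM+. The 4 IgA libraries held 35747242, 29542267, 27112947 and 26909987 reads for replicates 1 to 4, and the 4 IgM libraries 29177469, 24157439, 30578889 and 30705313 reads. The median guide had 236 to 319 reads per library. Guides without a read made up between 0.686% (95% interval 0.629 to 0.745) in IgA replicate 4 and 1.13% (1.05 to 1.20) in IgM replicate 1. A floor of 3 reads stood for 0.0917 to 0.124 CPM. The Gini index, a measure of uneven guide abundance, was 0.453 ± 0.0385 (SD, n = 4) in IgM and 0.428 ± 0.0481 (SD, n = 4) in IgA, and higher in IgM in 4 of 4 pairs (exact sign-flip test over pairs, p = 0.125, the smallest that 4 pairs allow, adjusted p = 0.167 over 4 measures; unpaired exact permutation test, p = 0.429, adjusted p = 0.714). Guides without a read and the share of the 100 most abundant guides were also higher in IgM in 4 of 4 pairs, with the same sign-flip p.

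Guides assigned to Batf, a transcription factor of the AP-1 family, were several-fold more abundant in IgM+ than in IgA+ cells in all 4 replicate pairs. Its 4 guides together had 445 ± 180 CPM in IgM (SD, n = 4) and 103 ± 32.3 in IgA (SD, n = 4), a log2 ratio of 2.09 ± 0.38 over pairs (SD, n = 4). The exact two-sided permutation test gave p = 0.0286 (adjusted p = 0.0286 over the 3 genes assigned in this way), the smallest that 4 against 4 libraries allow, and the exact sign-flip test over pairs gave 0.125, the smallest that 4 pairs allow. The permutation test takes all 8 libraries as exchangeable, which libraries paired by number are not, and only the sign-flip test keeps the pairs. The assignment was made from the size of the fold, so the tests describe the spread between libraries and are not independent evidence of a difference.

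**Figure D1:**
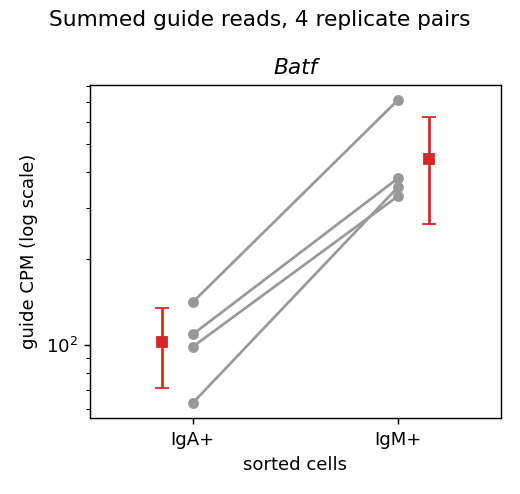
Summed guide CPM (log scale) for Batf in IgA+ and IgM+ cells; grey lines join the libraries of a replicate number and red squares show the mean with SD (n = 4). All 4 pairs rise from IgA to IgM, with a mean log2 ratio of 2.09.

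All 4 Batf guides were higher in IgM in every pair, with mean log2 ratios from 1.73 to 2.39. The guide AGAGATCAAACAGCTCACCG had a log2 ratio of 2.39 ± 0.67 over pairs (SD, n = 4), and AGGGGGTACCTGTTTGCCAG had 2.02 ± 0.11 (SD, n = 4). The lowest ratio, 1.73 ± 0.57 (SD, n = 4), belonged to GTGGGTACTCACCAGGTGAA. Positions of these guides in the genome were not analysed here.

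In the authors' deposited table, 46 genes passed an FDR of 0.05 toward IgM and 2 toward IgA, among 19673 genes. The 46 had log2 folds of at least 0.54 with a median of 0.99, per the authors' deposited table. Batf (1.99) and the B cell transcription factor Irf4 (1.74) had the largest log2 folds of the genes named here in the authors' deposited table. Foxo1 (1.51), a transcription factor restrained by PI3-kinase signalling, and Junb (1.49), an AP-1 partner of Batf, came next in the authors' deposited table. For 20 genes, these 4 among them, the authors' deposited table gave the same smallest p of 2.39e-07 and an FDR of 0.000248. Atxn7l3, a subunit of the deubiquitinating part of the SAGA complex, had a log2 fold of 1.32 in the authors' deposited table. Toward IgA, the authors' deposited table called Psmb3, a proteasome subunit (log2 fold -0.91, FDR 0.0149), and Zfp296, a zinc finger protein (-0.86, FDR 0.0371). Daxx (-1.04), Rpl18 (-1.57) and Dnaaf2 (-0.69) had the next smallest p and did not pass, each with an FDR of 0.151 in the authors' deposited table.

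The list of excision and mismatch repair lay toward IgM. Of 22 measured genes of base excision and mismatch repair, 5 passed toward IgM and 0 toward IgA in the authors' deposited table, and 6 passed toward IgM when adjusted over the list alone (cameraPR adjusted p = 1.13e-07). Among the 5 were the mismatch recognition gene Msh6 (log2 fold 1.47), the exonuclease gene Exo1 (1.33) and the uracil glycosylase gene Ung (0.99, FDR 0.00976), all from the authors' deposited table. In the list of class switching, 3 of 38 genes passed toward IgM in the authors' deposited table, Ung and Fam72a (1.28) among them, and 6 toward IgM and 1 toward IgA when adjusted over the list alone (cameraPR adjusted p = 0.00613, and 0.289 without the genes past the threshold). Among 29 genes of 53BP1, shieldin and DNA damage signalling, only Ercc6l2 passed (0.95, FDR 0.000619), and Trp53bp1 did not (0.43, p = 0.0157, FDR 0.954), in the authors' deposited table. That list did not pass (cameraPR adjusted p = 0.0962), nor did 11 genes of non-homologous end joining, with 0 called and Xrcc5 at 0.75 (FDR 0.29) in the authors' deposited table (cameraPR adjusted p = 0.232).

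The TGF-beta and IL-4 lists, for the added cytokines, also lay toward IgM. In the TGF-beta list, 5 of 32 genes passed toward IgM and 0 toward IgA in the authors' deposited table, and 9 when adjusted over the list alone (cameraPR adjusted p = 6.46e-07). They were the transcription factor subunits Cbfb (log2 fold 1.47) and Runx3 (1.29), the signal transducers Smad2 (1.47) and Smad4 (1.13) and the receptor gene Tgfbr1 (1.40), in the authors' deposited table. Tgfbr2, the partner receptor, had 0.46 with an FDR of 0.29 in the authors' deposited table. In the IL-4 list, 3 of 19 genes passed toward IgM in the authors' deposited table and 7 when adjusted over the list alone (cameraPR adjusted p = 2.16e-05). These were the receptor genes Il4ra (1.33) and Il2rg (0.59) and the transcription factor Stat6 (1.11), in the authors' deposited table. Of 33 genes of CD40 and NF-kappaB signalling, 0 passed in the authors' deposited table, where Cd40 had 0.52 (p = 0.00311, FDR 0.525), and the list did not pass (cameraPR adjusted p = 0.27). All 5 lists called toward IgM lost the call without their members past the threshold; for TGF-beta, IL-4 and repair the adjusted p was then 0.185, 0.176 and 0.249. Taking out members called on one side itself pushes the rest toward the other side.

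**Figure D2:**
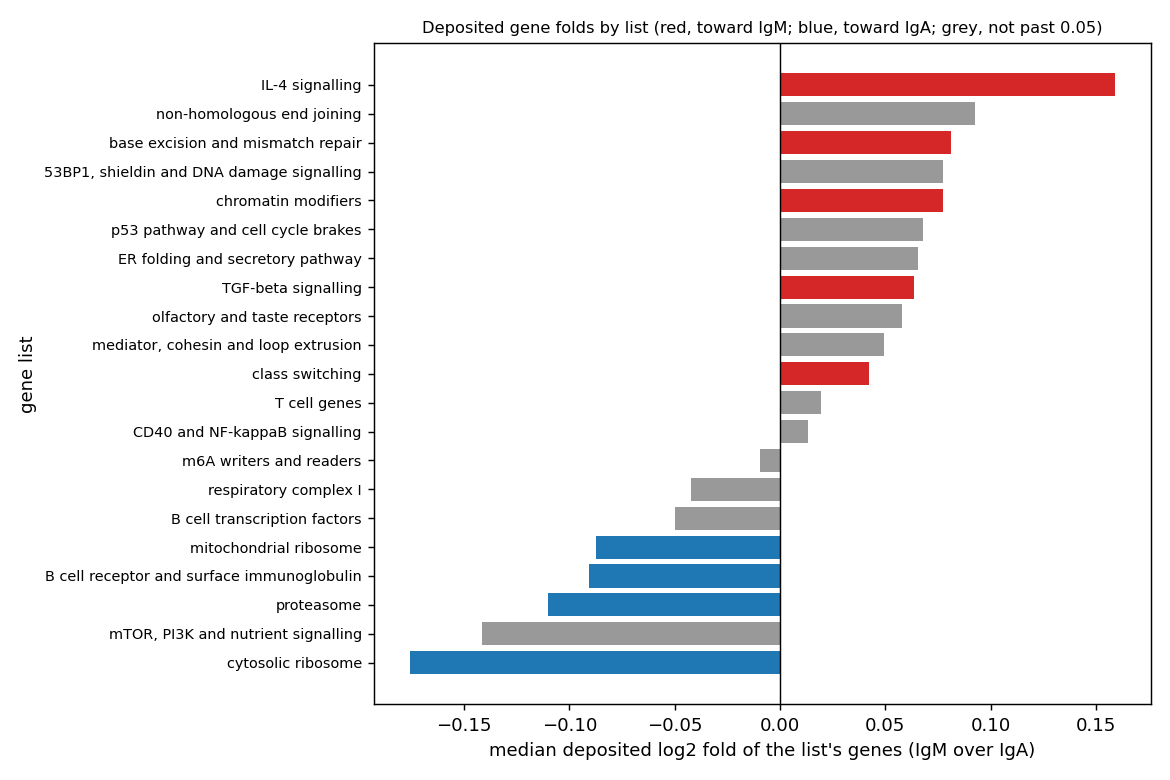
Median deposited log2 fold of the genes in each of 21 lists (x axis, IgM over IgA); red and blue bars mark lists past an adjusted p of 0.05 toward IgM and IgA, grey bars the rest. The medians run from -0.18 for the cytosolic ribosome to 0.16 for IL-4 signalling.

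Chromatin modifiers held 3 of 45 genes past the threshold toward IgM in the authors' deposited table, the acetyltransferase genes Crebbp (0.59) and Ep300 (0.73) and the demethylase gene Kdm1a (0.80), with 6 adjusted over the list alone (cameraPR adjusted p = 0.0441, and 0.396 without the genes past the threshold). Among 33 B cell transcription factors, 3 passed toward IgM, and adjusted over the list alone 6 lay toward IgM and 5 toward IgA, per the authors' deposited table (cameraPR adjusted p = 0.937). Of 29 genes of mTOR and PI3K signalling, 2 passed toward IgM, Foxo1 among them, and adjusted over the list alone 3 lay toward IgM and 4 toward IgA in the authors' deposited table (cameraPR adjusted p = 0.305). The authors' deposited table called 0 of 32 genes of ER folding (cameraPR adjusted p = 0.0754), 0 of 40 of mediator and cohesin (0.207), 0 of 32 of the p53 pathway (0.546) and 0 of 15 of m6A modification (0.937).

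Lists of genes for protein synthesis and turnover lay toward IgA. The cytosolic ribosome list had a median log2 fold of -0.18 over 85 genes, of which 0 passed over all genes and 11 toward IgA when adjusted over the list alone, in the authors' deposited table (cameraPR adjusted p = 4.58e-05). Rpl18 and Rplp1 (-0.89, FDR 0.169) had its smallest p in the authors' deposited table. The proteasome list had -0.11 over 40 genes, with 1 called toward IgA and 6 adjusted over the list alone, in the authors' deposited table (cameraPR adjusted p = 0.00518). The mitochondrial ribosome list had -0.09 over 76 genes, with 0 called, in the authors' deposited table (cameraPR adjusted p = 0.0138). Of 22 genes of the B cell receptor and surface immunoglobulin, 0 passed in the authors' deposited table (median -0.09, cameraPR adjusted p = 0.0441), where the phosphatase gene Inpp5d had the smallest p toward IgM (0.55, FDR 0.0781), and of 42 genes of respiratory complex I, 0 passed (cameraPR adjusted p = 0.0545). Genes a B cell line does not need were not called in the authors' deposited table. Of 1427 olfactory and taste receptor genes 0 passed (median 0.06, cameraPR adjusted p = 0.27), and of 23 T cell genes 0 (cameraPR adjusted p = 0.789). The receptor genes leaned toward IgM, with 899 folds above 0 and 528 below in the authors' deposited table. Over all genes the median there was 0.004. With a preset correlation of 0.05, 4 of the 9 list calls held, those of repair (adjusted p = 0.000153), TGF-beta (0.00109), IL-4 (0.00165) and the cytosolic ribosome (0.0426).

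The count table was also tested without the authors' gene names. In the rank test, 42 runs of 4 guides passed toward IgM and 0 toward IgA, and 50 and 0 with the replicate block. Leaving out 1 library gave 17 to 40 runs toward IgM, and fry over the same runs, run only without the block, gave 0. Of the 42 runs, 35 shared guides with a run called with the block. Single guides gave 0 calls in either direction without the block in edgeR (220 of 78708 guides at an unadjusted p under 0.05). In simulated counts this test recovered 0% of guides changed by 1 or 2 log2 units, so its 0 calls cannot speak against effects. DESeq2 without the block gave 12 toward IgM. With the replicate block, edgeR called 70 guides toward IgM and 0 toward IgA; with a replicate number left out, a setting chosen after seeing the data, 33 to 64 passed toward IgM. In simulated counts with the block, 70.9% of guides raised by 1 log2 unit were recovered and 45% of those lowered by 1. On summed counts, 0 runs passed without the block in edgeR (277 at an unadjusted p under 0.05), 12 passed toward IgM with DESeq2, and 99 toward IgM and 10 toward IgA passed with the block (60 to 94 and 2 to 5 with a replicate number left out). In simulated counts with the block, the last test also called 34 unchanged runs. The common dispersion was 0.316 without and 0.0663 with the block.

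Control guides, which target no gene, gave the background. Of 980 control guides kept, 0 passed with or without the block in edgeR. With the block 8.06% had an unadjusted p under 0.05, against 8.10% of 77728 targeting guides, and without it 0.102% of control guides. Sound p-values would put a share of about 0.05 of control guides there. Those with the block thus ran too small, and its calls may hold more false ones than the FDR states. Without the block, control guides had a median log2 fold of -0.02 with an SD of 0.32 across guides. The SD across targeting guides was 0.36. The log2 fold varied with read number in both kinds of guide. With the block, control guides with a mean of 50 to 100 reads had a median of -0.48 (SE 0.07, 51 guides) and those with 400 reads or more 0.07 (SE 0.01, 491 guides).

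**Figure D3:**
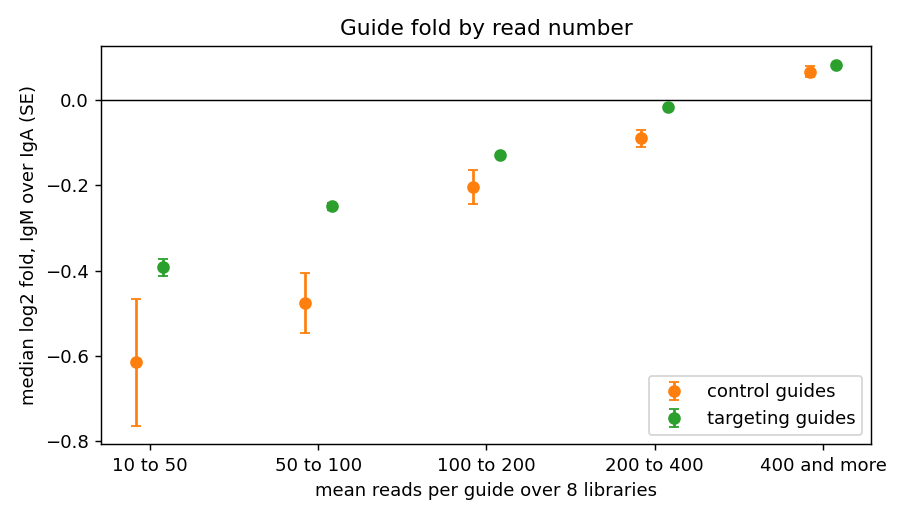
Median log2 fold (IgM over IgA, replicate block) of control and targeting guides by mean reads per guide over 8 libraries; bars show the SE of the median. Control guides run from -0.62 at 10 to 50 reads to 0.07 at 400 reads or more, and targeting guides from -0.39 to 0.08.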

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

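The tests of read number and of centring were chosen after the result was seen; those over other splits of the libraries were fixed before it, apart from holding the count without the block to the splits that part all pairs. Of 14 sets of 4 libraries checked for a library far from the others, 4 had one, where chance gives about 1 in 20. The sets are not independent, since measures share libraries and libraries of the same number deviated together. The 4 flags thus do not establish an excess over chance. In IgA replicate 1 the most abundant guide had 46989 reads, against 7105 in the next library. The 100 most abundant guides took 2.28% of reads in IgA replicate 1 (next 0.994%) and 2.57% in IgM replicate 1 (next 1.20%). Guides assigned to Batf had 713 CPM in IgM replicate 4 (next 381), and without replicate 4 the Batf log2 ratio was 2.01.

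The lists of the ribosome and the proteasome lay toward IgA. A shift of the centre of the deposited folds would move all lists alike. Yet the cytosolic ribosome median differed from that of the olfactory and taste receptors by -0.23 (permutation p = 0.0001, the smallest that 10000 permutations give). The ribosome list was picked because it lay toward IgA, and the permutation used the same deposited folds, with genes taken as exchangeable. Its p is thus no independent evidence for the lean toward IgA. The receptor list itself had a median of 0.06, against 0.004 over all genes. Guides with few reads may lie toward IgA whatever they target: control guides with a mean of 50 to 100 reads had a median log2 fold of -0.48. Targeting guides at that read number had -0.25, above control guides by 0.23 (SE 0.07). Guides against genes that cells need to grow would be depleted and so have few reads, but the guides of these genes were not known, so this explanation stays open. A biological difference between IgM+ and IgA+ cells in their need for these genes was not tested.

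The 42 runs of the rank test exceeded every other split of the 8 libraries: 1 of 35 splits, the real one, gave as many, and the highest of the others gave 14. The bound set beforehand took the libraries as exchangeable, but libraries of the same number deviated together (correlations of 0.73 to 0.787), so only the 8 splits that part all 4 pairs are alike, too few for a share under 0.05. Among the 7 others of these, the 4 that swap 1 replicate number keep part of the isotype difference and gave 2 to 14 runs, and the 3 that swap 2 numbers gave 0. For single guides and for summed counts without the block the real split gave 0 calls. Any count reaches 0, so all 35 of 35 splits gave as many and the comparison decides nothing. The highest of the others gave 1284 guides and 1291 runs. The 3 splits that part no pair gave 719 to 1284 guides, which points to the pairing of libraries by number. With the block, the same 8 splits are too few for a share under 0.05. There 1 split, the real one, gave as many as its 70 guides, 50 rank-test runs and 109 summed runs, and the highest others gave 1, 9 and 0.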

How the results depend on the processing

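The block with a replicate left out and all list settings below were chosen after seeing the data. The replicate block moved single guides from 0 to 70 toward IgM, and summed runs from 0 to 99 toward IgM and 10 toward IgA; the rank test, with 50 runs, changed by less than 1.5 times. DESeq2's Wald test gave 12 guides and 12 summed runs toward IgM. With the block and a replicate number left out, 64, 37, 39 and 33 guides passed toward IgM without replicates 1 to 4, with 94, 60, 64 and 61 summed runs toward IgM and 2, 2, 3 and 5 toward IgA. Leaving out libraries gave 17 to 45 rank-test runs toward IgM. It was 22, 22, 17 and 24 without IgA replicates 1 to 4. Without IgM replicates 1 to 4 it was 40, 26, 32 and 26. With both libraries of a replicate number left out and no block, 42, 32, 29 and 29 runs passed without replicates 1 to 4. The number of samples alone thus does not order these counts, and the cause was not tested. Toward IgA the rank test gave 0 to 2 runs with libraries left out, 2 of them without IgA replicate 1 or without replicate 1, and 2 with a minimum mean of 50 reads; the cause was not tested. In edgeR without the block, summed runs toward IgM numbered 0 to 1 with libraries left out, 1 without replicate 1. With fry, run only without the block, 0 runs passed in place of 42. The guide and summed tests in edgeR without the block also gave 0. In simulated counts without the block, the guide test recovered 0% of guides changed by 1 or 2 log2 units. The summed test recovered 0% of runs changed by 1 and 68% of those changed by 2. The 0 calls of these tests thus cannot speak against effects of about 1 log2 unit. Fry was not run on simulated counts, and the cause of its 0 runs was not tested. At an FDR of 0.25 the authors' deposited table held 75 genes toward IgM and 12 toward IgA.

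With a preset correlation of 0.05, 4 lists passed in place of 9. Adjusted p rose to 0.105 for class switching, 0.214 for the B cell receptor, 0.263 for chromatin modifiers, 0.223 for the mitochondrial ribosome and 0.105 for the proteasome. Leaving out the members past the threshold takes them from one side, which itself pushes the rest toward the other. Adjusted p was then 0.289 for class switching, 0.249 for repair, 0.185 for TGF-beta, 0.176 for IL-4, 0.0662 for the B cell receptor (its adjustment changed, its members did not) and 0.396 for chromatin modifiers. It was 0.0497 for B cell transcription factors and 0.0321 for mTOR signalling, toward IgA, with only members called toward IgM taken out, so these are not counted as calls. With the deposited log2 fold as the statistic, end joining (0.00822) and the olfactory and taste receptors (0.0408) passed toward IgM. Scaling, the other read minimum and the rank test's settings changed no other count by over 1.5 times, and the log2 ratio of Batf moved by less than 1 SD. Not run, because guides and genes were not paired, were an estimated correlation, the block, scaling and left-out replicates for the lists, and most named genes under each setting. No setting for ambiguous reads was run, because the count table marks none.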

Other observations

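The genes here were chosen after their values were seen, and no test of the groups was run, since their members were picked for their folds. Of 23 SAGA subunits, paralogs included, 3 passed toward IgM and 0 toward IgA in the authors' deposited table, with a median log2 fold of 0.11 and a range from -0.32 to 1.32. They were Atxn7l3, Usp22 (0.99, FDR 0.000248), the deubiquitinase, and Taf5l (0.73, FDR 0.000619), while Kat2a, the acetyltransferase, did not pass (0.08), in the authors' deposited table. Kti12, a partner of the Elongator complex that modifies transfer RNA, passed with a log2 fold of 1.08 (FDR 0.026) in the authors' deposited table. The Elongator subunits Elp5 (0.60), Ikbkap (0.55), Elp4 (0.49), Elp6 (0.47), Elp3 (0.39) and Elp2 (0.33) all had folds above 0 and did not pass in the authors' deposited table, with Ikbkap nearest at an FDR of 0.0963.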
